A study of Mus musculus with 2 samples.

How the data were processed

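DNase-seq maps open chromatin by sequencing the ends of fragments that DNase I releases from nuclei. It was applied to gastrocnemius, the large calf muscle, of male mice of the hybrid strain B6CASTF1/J aged 10 days. There was 1 group with 2 libraries, which the labels call biological replicates 1 and 2, each with technical replicate number 1. Both labels give the same donor record and name 3 males per sample, and whether tissue of those animals was pooled is not stated in them. Differences between the libraries therefore measure only the spread between these samples, part of which can be technical. With a single group, no comparison of conditions was possible, and the comparisons made were between the replicates, between parts of the genome and between sets of genes.

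Per the sample notes deposited with the files, each library had its own peaks, footprints and false discovery rates, made from its filtered alignments to mm10, with no pooling of replicates. The mice carry CAST alleles as well, and whether reads of these mapped less often to this B6 reference, which would lower peak values and listed bases, was not analysed here. The aligner, the peak caller, the footprint caller and their versions are not given in the sources used here. The deposited peak value is a signal scaled to library depth by the authors, per the values: in each library 100% of the values were whole multiples of one small step, within 0.05 of a step, as tag counts scaled to a common depth would be. The step was 0.00544 in replicate 1 and 0.00587 in replicate 2, and the window in which tags were counted is not given in the sources used here. With 1 tag per step the median peak rested on 134 tags in replicate 1 and on 122 in replicate 2, and the lowest on 8 and 6. Such counts of cleavage events can hold copies made by PCR, so intervals cover counting error only. The per-position files hold a p-value type of number, the FDR as deposited by the authors, and list only positions under 0.05. Bases at that FDR are called listed bases here. Of the 2 deposited peak sets per library, every peak of the wider one held a listed base and every peak of the stricter one a base under an FDR of 0.001; the wider set was used unless stated. Footprints, short stretches protected from cleavage inside open chromatin, carry the same value of 0.01 on every line, so only their positions were used.

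Analyses were limited to chromosomes 1 to 19, X and Y of mm10. Genes and transcription starts came from GENCODE M21, without pseudogenes, and sequence, soft-masked repeats and chromosome lengths came from the matching GRCm38 assembly. Peaks counted as shared when they overlapped by at least 1 bp, and the rate expected by chance came from 20 random placements of the peaks on their own chromosomes. A peak was promoter-proximal when its midpoint lay within 500 bp of any annotated start and distal when it lay over 5 kb from every start. The promoter of a protein-coding gene was open when a peak overlapped the 500 bp on either side of one of its coding transcripts' starts, and its value was the highest such peak. A peak near the starts of neighbouring genes counted for each of them. Which start a promoter value belongs to was not examined. Locus cover was the percentage of listed bases in the gene body plus 10 kb on each side. Regions listed in both replicates were joined over gaps of up to 150 bp before their width was measured.

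Gene lists and motifs were fixed before the data were examined, as were the tests, the rule for naming genes and the alternative settings, apart from those named as added. The 26 lists cover fast and slow myofibres, developmental sarcomere genes, pan-sarcomere and triad genes, myogenic transcription factors, the neuromuscular junction, satellite cells, fibro-adipogenic progenitors with fibroblasts, tendon, endothelium, pericytes with smooth muscle, macrophages, lymphocytes, Schwann cells, erythroid cells, adipocytes, cardiac muscle, hepatocytes, neurons, germ cells, photoreceptors, pancreas, keratinocytes, housekeeping genes, hindlimb position, and forelimb and head position. All 346 symbols on them matched the annotation. Lists were tested at promoters with a two-sided Fisher's exact test against all other protein-coding genes. Locus cover was tested with a two-sided permutation test against 10000 random lists matched on locus length. Each family of tests was adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Genes and sites are not replicates, so these tests describe the 2 libraries only.

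The 25 consensus motifs were searched on both strands. Footprints were set against windows of the same length moved by 100 bp within the same listed region and free of footprints, and a call needed an adjusted p under 0.05 in both replicates in the same direction. Motifs in shared promoter-proximal and distal peaks were searched in 150 bp around the midpoint. Both used two-sided Fisher's exact tests, and odds ratios were computed with 0.5 added to each count. Up to 20 shuffles of each consensus gave the odds ratios that its letters give in another order. Differences between the replicates were medians over a list of the log2 ratio of promoter value, replicate 2 over replicate 1, centred on all promoters open in both and set against 10000 random lists matched on mean value.

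Named genes were those at the 20 widest regions listed in both replicates and nearest the 15 highest shared peaks, up to 4 members of each list with the highest promoter values and those without a promoter peak, the skeletal myosin heavy chain genes, Myod1, Myog, Myf5, Myf6, Pax7, Pitx1, Tbx4 and Tbx5, up to 5 genes in each direction with the largest replicate difference, and up to 5 motifs in each direction.

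Alternatives were another overlap rule, equal numbers of peaks, the stricter threshold, windows of 1000 bp at promoters and 50 kb at loci, each replicate alone, peaks above the median value, classes of CpG or GC content, other control windows, distal footprints alone and quantile normalization. Further ones were added after the data had been seen and are named as such where they appear. The statistical steps were tested on simulated data with large changes. Of 5 lists raised to 95% open and 5 lowered to 10% among 21000 simulated genes, the promoter test called 5 and 5. It called none of 20 unchanged lists. The locus cover test called 5 of 5 lists raised by about 1 SD and none of 25 unchanged ones. Smaller changes were not simulated, so a list that did not pass may still differ. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.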

Results

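Open chromatin was mapped by DNase-seq in gastrocnemius muscle of B6CASTF1/J male mice aged 10 days, in 1 group of 2 biological replicates. Replicate 1 had 123255 peaks, 310961 footprints and 35695993 listed bases, 1.35% of the sequenced genome. Replicate 2 had 150088 peaks, 373154 footprints and 43782204 listed bases, or 1.65%. The median peak value was 0.729 in replicate 1 and 0.716 in replicate 2, in the deposited depth-scaled signal. Values below are given for replicate 1 and then replicate 2 unless stated.

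The widest stretches of open chromatin found in both replicates lay mostly over gene starts. The widest spanned 6053 bp at chromosome 5, positions 57714597 to 57720649 in mm10, over the start of Pcdh7, a protocadherin. Next came 5953 bp at Plec, which encodes the cytolinker plectin of the myofibre Z-disc, 5681 bp at Irs1, an adaptor of insulin and IGF signalling, 5658 bp at Marcks and 5535 bp at Nfatc4. Zfp503, Hdac5, Dbp and Tns1 completed the 9 regions of at least 5000 bp, against a median of 240 bp over 88204 regions. The remaining ones of the 20 widest lay at Brd2, Parp3, Mex3b, Actg1, Ptma, Myc, Jun and Nfic and in intergenic sequence nearest the starts of Tnrc18, Zfp36l2 and Azin1. At Hdac5 and Tns1 the region lay inside the gene, 11917 and 15058 bp from the nearest start.

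The highest shared peaks, ranked by the geometric mean of both values, lay elsewhere. An exon of Lars2 on chromosome 9, positions 123461921 to 123462080, led with values of 46.3 and 35.7, and the promoters of Hjurp (30.9 and 52.4) and Dynlt1b (26.9 and 56.2) were close behind. Peaks at the starts of Bahcc1, Mplkip, Nup107 and Amd1, in introns or exons of Mid1, Kpna1 and Cers5, and far from coding genes near Igf2bp3 and Gm15319 were also among the 15 highest. Another, at chromosome 17, positions 39846781 to 39846880, lay in an annotated ribosomal RNA. Peaks near Gm10719 (82.7 and 18.1) and Gm11168 (55.0 and 17.3) at the end of chromosome 9 were 98.1% and 100% soft-masked repeat, where reads from many copies of a repeat can map to 1 place.

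Most strong sites were found in both libraries, and most of the disagreement was among weak ones. Of the replicate 1 peaks, 78.2% overlapped a replicate 2 peak, and of the replicate 2 peaks 64.1% overlapped one of replicate 1 (95% binomial intervals 78.0% to 78.5% and 63.8% to 64.3%). These are both directions of 1 comparison, and differ with the number of peaks. Random placement gave 2.19% and 1.78%. In the highest 10% of peaks by value, 99.5% were found in the other library in both directions, and in the lowest 10% it was 24.6% and 21.9%. With the same number of highest peaks from each library the shares were 72.8% and 72.5%. Among listed bases, 83.9% of those in replicate 1 and 68.4% of those in replicate 2 were listed in both, with a Jaccard index of 0.604. Across 96434 shared peaks, Spearman's rho between the deposited values was 0.893, and 0.809 among those above the median value. This describes sites within 2 libraries, and sites are not independent replicates.

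**Figure D1:**
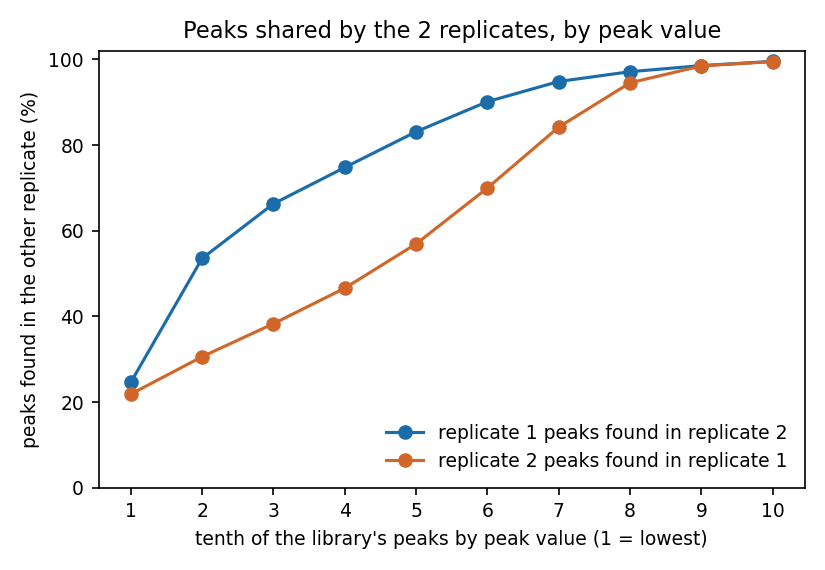
Percentage of peaks found in the other replicate (y axis) for 10 classes of equal size by peak value (x axis, 1 is the lowest), with replicate 1 in blue and replicate 2 in orange. The shares rose from 24.6% and 21.9% in the lowest class to 99.5% in the highest.

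Promoters held far more of the open sites than their share of the genome. Of the shared peaks, 22.9% lay within 500 bp of an annotated start, a stretch that makes up 1.77% of the genome, a ratio of 12.9. Introns held 39.4% of the shared peaks, intergenic sequence 30.9% and exons 6.84%, against 40.9%, 54.3% and 3.05% of genome bases. The promoter share was 20.4% over all replicate 1 peaks and 16.7% over all replicate 2 peaks, and it was lower among peaks of 1 library alone, at 11.4% for replicate 1 and 5.68% for replicate 2. The range between the 2 libraries is far smaller than the distance of either from the genome share.

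On the X chromosome, of which male cells carry a single copy, peaks were sparse. Replicate 1 had 21.7 peaks per Mb there against a median of 51.8 over the 19 autosomes, and replicate 2 had 25.9 against 61.7. The ratios of 0.419 and 0.420 lay below the ratio of 0.722 for protein-coding genes. Among peaks above the median value the ratios were 0.234 and 0.235. The lowest autosome had 38.8 and 47.2 peaks per Mb, above X in each library. X peaks also had lower values, with medians of 0.392 and 0.393 against 0.740 and 0.728 on autosomes.

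Which cell identities the open promoters recorded was asked with the fixed gene lists. Muscle regulators and the sarcomere stood open together, though mostly not at high values. Averaged over both replicates, open promoters of myogenic factors had a median value of 3.35 and those of the sarcomere list 2.06. All promoters open in both had a median of 5.56. All 14 myogenic transcription factors had a promoter peak in both replicates, with the highest values at Mef2a (10.3 and 14.7), Mef2d (8.89 and 12.5) and Srf (5.23 and 13.9). Of 26 pan-sarcomere and triad genes, which build the contractile unit and its calcium release sites, 24 were open, led by Jph1 (5.91 and 9.81), Des (4.91 and 8.79), Actn2 (3.90 and 6.23) and Acta1 (3.10 and 6.42), while the M-band gene Myom2 had no promoter peak in either library. Housekeeping promoters were open in 18 of 18 cases, led by Eef2 (21.4 and 22.1), Rplp0 (14 and 19.9), Psmb2 (15.9 and 16.7) and Ppia (13 and 16.6). All 11 pericyte and smooth muscle promoters were open, led by Cspg4, Myh11, Mcam and Pdgfrb with values between 1.80 and 4.77.

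Over all protein-coding genes, 14267 of 21911 promoters, or 65.1%, were open in both replicates. Two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over the 26 lists called 4 lists higher, at adjusted p = 0.0115 for the myogenic factors, 0.0112 for the sarcomere list, 0.00360 for housekeeping genes and 0.0257 for pericytes with smooth muscle. Promoters rich in CpG are open in most tissues, and within classes of CpG content the myogenic factors (adjusted p = 0.164 by the exact test) and housekeeping genes (0.726) no longer passed. Fast myofibre genes, open in 17 of 19 cases against 32.7% expected for their CpG classes, passed only in that form of the exact test, at adjusted p = 6.6e-08 against 0.0616 without classes, apart from replicate 2 alone (0.0191). Among peaks above the median value the sarcomere list (adjusted p = 0.308, Fisher's exact test), the myogenic factors (0.143) and pericytes with smooth muscle (0.378) did not pass, and the last did not in replicate 1 alone (0.0590).

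Fast fibre promoters were led by Mylpf (8.48 and 11.5), the fast regulatory light chain, Ckm (6.06 and 9.60), Pygm (5.98 and 9.64) and Mylk2 (3.92 and 5.15). Mylpf also had the highest promoter CpG content of the fast list, an observed to expected ratio of 0.838. Whether its peak belongs to the start of a neighbouring gene was not examined. Among slow fibre genes, 7 of 13 were open in both replicates, with Atp2a2 (6.97 and 9.40), Tpm3 (3.50 and 9.46), Tnnt1 and Mb highest, and Myh7, Myh7b, Tnni1, Tnnc1 and Myl2, mainstays of the slow sarcomere, had no promoter peak in either. The slow list did not differ from other genes (adjusted p = 0.50, Fisher's exact test). Developmental sarcomere genes were open in 6 of 11 cases, led by Myl4 (13.9 and 13.1), Ncam1, Igf2 and Actc1, and in 10 cases in replicate 2. Neuromuscular junction genes were open in 11 of 13 cases, led by Etv5 (11.9 and 19.9), a factor of synaptic nuclei, and by Chrnb1 (5.07 and 11.4), Utrn and Etv4. Neither list passed the test in both replicates, and the junction list, with all 13 open in replicate 2, passed there alone (adjusted p = 0.0191, Fisher's exact test).

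Among other cells of muscle tissue, satellite cell, fibroblast, tendon, endothelial and Schwann cell promoters were mostly open, and erythroid, adipocyte and macrophage promoters mostly closed. Of these lists only the macrophage one passed the test against all genes on the count in both replicates, as lower. The lymphocyte list, given below, did so too. Satellite cell promoters were open in 12 of 13 cases, led by Hey1 (8.72 and 14.2), Megf10, Sdc4 and Cdh15, and in replicate 1 alone, with all 13 open, the list passed as higher (adjusted p = 0.0240, Fisher's exact test). Fibroblast and fibro-adipogenic progenitor promoters were open in 12 of 15 cases, led by Col1a1 (5.00 and 9.75), Osr2 (4.57 and 8.42), Pdgfra (5.25 and 5.57) and Col1a2 (2.63 and 5.81), without a peak at Ly6a, and this list passed within CpG classes (adjusted p = 0.00830, exact test). Tendon genes were open in 7 of 9 cases (Egr1, Mkx, Scx and Col11a1 highest), endothelial genes in 12 of 14 (Egfl7, Flt1, Esam and Kdr), Schwann cell genes in 9 of 12 (Egr2, Pmp22 and Erbb3 among them), erythroid genes in 4 of 10 (Epor and Ank1) and adipocyte genes in 3 of 9 (Lipe and Pparg, without a peak at Adipoq). Macrophage genes were open in both replicates in 2 of 14 cases, Laptm5 and Lyz2, but in 9 cases in replicate 2. The macrophage list was lower than other genes (adjusted p = 8.8e-04, Fisher's exact test) on the count in both, not in replicate 2 alone, where 64.3% were open (adjusted p = 0.815), nor within CpG classes (adjusted p = 1, exact test), which gave 16.4% where 14.3% were open.

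Promoters of lymphocytes, which the tissue could hold, and of tissues that a calf muscle should not hold were mostly closed, except those of the neuronal list, which were mostly open. None of 12 lymphocyte promoters was open in both replicates (adjusted p = 8.4e-05, Fisher's exact test with Benjamini-Hochberg adjustment, as for the values that follow), and 1 of 14 hepatocyte promoters was, Apob, with values of only 0.343 and 0.223 (1.4e-04). Open promoters numbered 1 of 12 in photoreceptors (6.6e-04), 3 of 12 in germ cells (0.0142), 3 of 13 in the pancreas (0.0106) and 3 of 12 in keratinocytes (0.0142). The single members with high values were Rom1 (5.42 and 8.39), Dazl (5.68 and 9.0) and Krt10 (5.73 and 8.90). Within CpG classes only germ cell, photoreceptor and pancreas lists stayed lower in the exact test, and with replicate 1 alone germ cell (adjusted p = 0.124, Fisher's exact test) and pancreas (0.0902) lists did not pass, nor did keratinocytes with either replicate alone. Neuronal genes, with 11 of 14 open, led by Camk2a (2.12 and 5.19), and cardiac genes, with 5 of 12 open and none at Nkx2-5 or Myh6, did not differ from other genes.

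Fast myofibre loci had 11.2% of their bases listed (10.8% and 11.5%) against 4.56% in random lists of the same lengths, a ratio of 2.44. Myogenic transcription factors had 8.69%, a ratio of 2.39, and pan-sarcomere and triad genes 5.91%, a ratio of 1.77. Housekeeping loci had 9.49%, a ratio of 2.04, and hindlimb position genes, which are Pitx1, Tbx4 and posterior Hox genes, had the most of the 26 lists at 20.9%, a ratio of 4.26. Hepatocyte loci had 1.55%, a ratio of 0.348. Two-sided permutation tests with Benjamini-Hochberg adjustment gave adjusted p = 0.0026 for fast fibres and hindlimb genes, the smallest that the 10000 random lists allow here, 0.0052 for housekeeping, 0.0091 for myogenic factors and 0.0165 for the sarcomere and hepatocyte lists. The other 20 lists did not pass, slow myofibres among them at 4.77%, a ratio of 1.17. Beside random lists matched also on CpG content, chosen after seeing the data, the hindlimb ratio was 2.60 and the fast myofibre ratio, then the highest, 3.45, and the housekeeping call (adjusted p = 0.135) and the hepatocyte call (0.384) were lost, and with bases listed in both replicates the sarcomere call was lost (0.0966, permutation test), as it was at the stricter threshold (0.0646). With 50 kb on each side of the gene, the myogenic and hepatocyte calls were lost (both adjusted p = 0.153, permutation test) and keratinocyte loci were lower, at a ratio of 0.291 (0.0052).

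**Figure D2:**
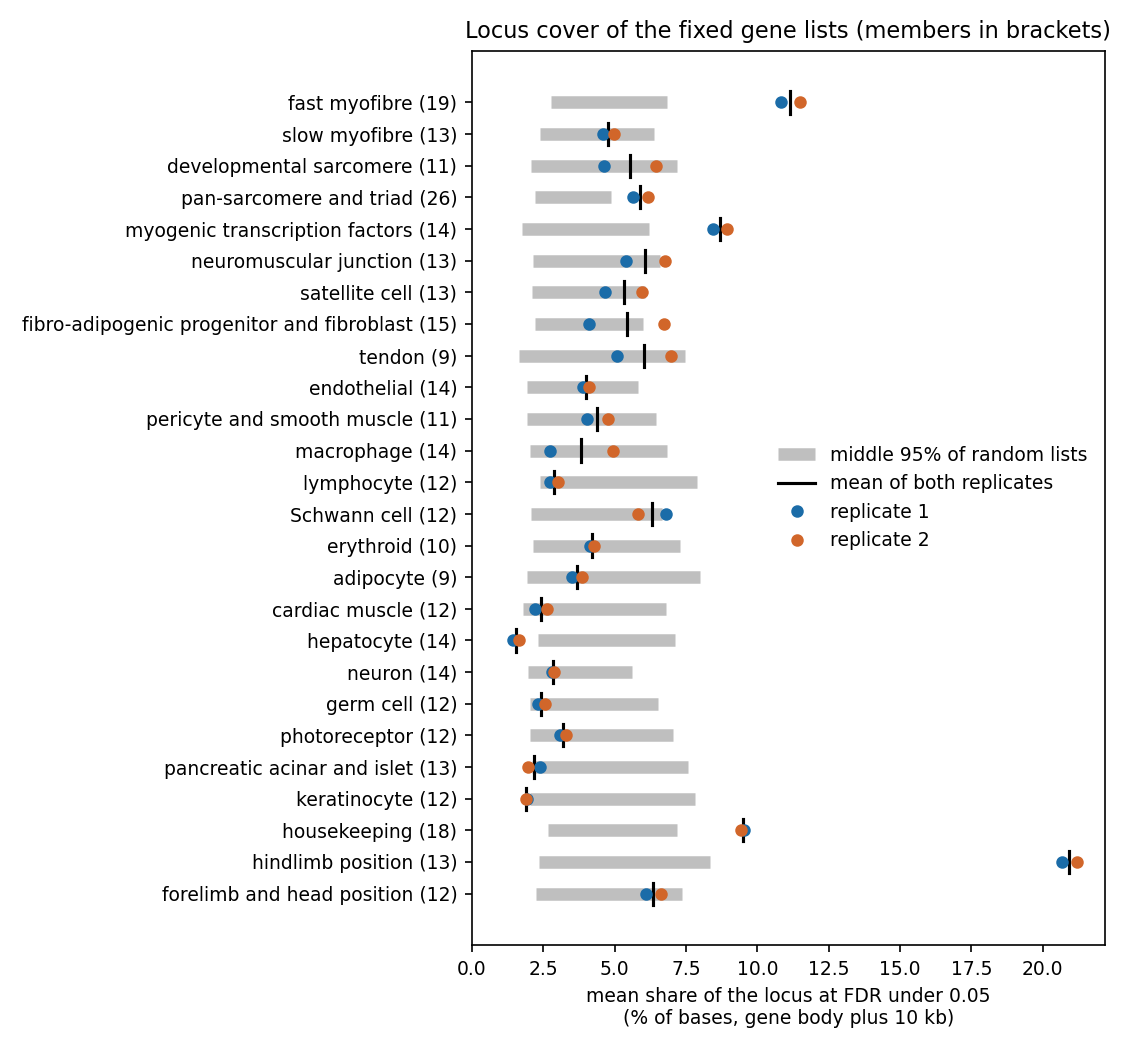
Mean percentage of listed bases per locus (x axis) for each fixed list (y axis, members in brackets), in replicate 1 (blue), replicate 2 (orange) and their mean (black line), over the middle 95% of 10000 random lists matched on locus length (grey). Hindlimb position (20.9%), fast myofibre (11.2%), housekeeping (9.49%), myogenic transcription factors (8.69%) and the sarcomere list (5.91%) lay above the grey range, and hepatocyte (1.55%) and keratinocyte (1.9%) lay below it, the last without passing the adjusted test.

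In the myosin heavy chain cluster on chromosome 11, Myh8, Myh4 and Myh1 were open at their starts. Myh8, the perinatal isoform, had promoter values of 1.45 and 1.14, Myh4, of type 2B fibres, 0.631 and 0.875, and Myh1, of type 2X fibres, 0.489 and 0.875. Myh2, of type 2A fibres, Myh3, the embryonic isoform, and Myh13, of eye muscles, had no promoter peak in either library, nor did the slow gene Myh7 on chromosome 14. The highest sites of the cluster lay away from the promoters. In the stretch from 67068300 to 67381586, with 32 and 42 peaks, a site at 67120781, 42601 bp past the Myh3 start, had 1.71 and 4.25, one at 67112101 had 3.8 and 3.14, and one inside Myh13 at 67350501 had 4.13 and 2.85. The 3 sites were picked by height after the values were seen.

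**Figure D3:**
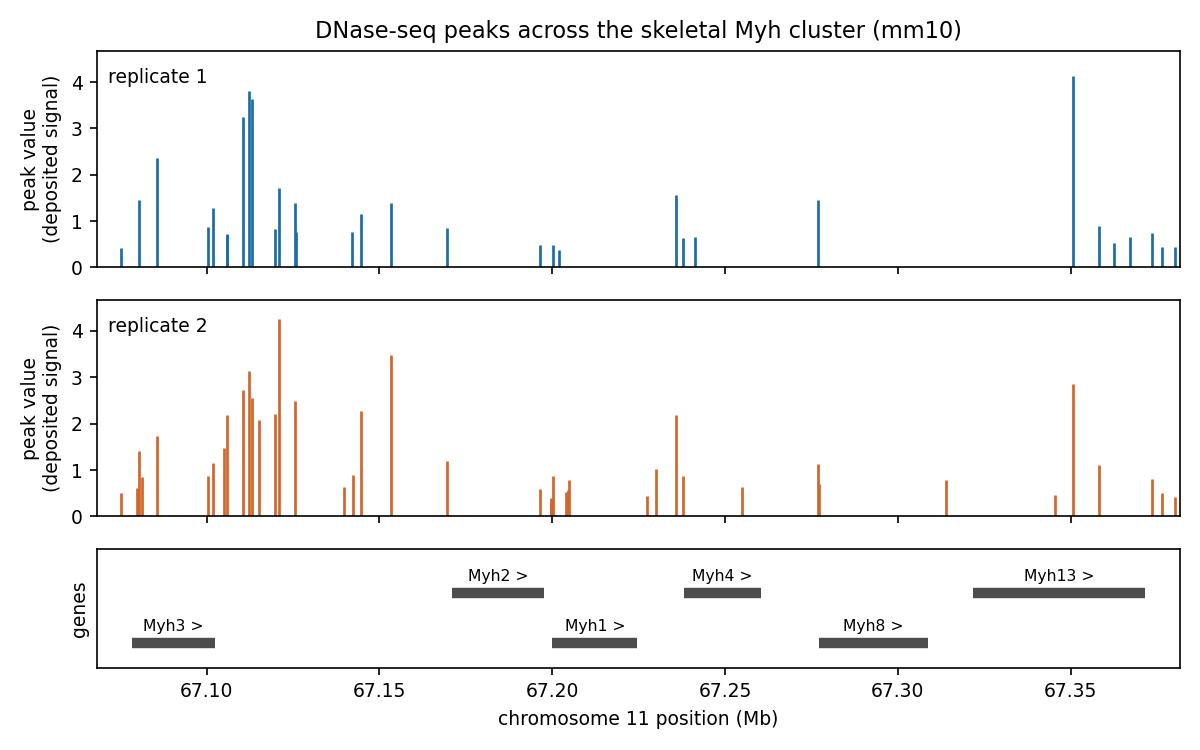
Peak values (y axis, deposited signal) along the skeletal Myh cluster of chromosome 11 (x axis, Mb, mm10) in replicate 1 (blue) and replicate 2 (orange), with the genes below and their direction as arrowheads. The highest peaks, up to 4.13 and 4.25, lie between Myh3 and Myh2 and inside Myh13, and not at gene starts.

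Among the myogenic determination factors, Myod1 had promoter values of 3.17 and 7.39 and Myog, which drives differentiation, 1.61 and 2.58. Myf5 (0.653 and 0.927) and its neighbour Myf6 (0.479 and 0.511) were lower. Pax7, the marker of satellite cells, had 1.32 and 1.46.

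Genes of hindlimb position had more of their loci listed than genes of forelimb and head position. Pitx1, which specifies the hindlimb, had promoter values of 1.15 and 1.21 with 12.6% and 14.3% of its locus listed, and Tbx4, its target in the hindlimb, had 1.55 and 1.46 with 3.88% and 7.77%. Tbx5, the forelimb counterpart, had no promoter peak and 0.594% and 1.02%. In the Hoxa cluster cover was highest at Hoxa9 (45.3% and 32.8%) and Hoxa10 (46.0% and 30.0%) and lower at Hoxa13 (12.4% and 4.95%), and Hoxc10 had the highest promoter values of the list, 10.7 and 12.8. The 13 hindlimb loci had a mean cover of 20.9% against 6.36% in 12 loci of the forelimb and head, including Hoxa4 and Hoxa5 (two-sided permutation test, p = 8.0e-05). This comparison of the lists was added after the data had been seen and was not matched on locus length. At promoters, 10 of 13 hindlimb and 7 of 12 forelimb and head genes were open, and neither list passed Fisher's exact test. With 50 kb on each side, the forelimb and head list also had more cover than random lists, a ratio of 2.05 (adjusted p = 0.0052, permutation test).

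Most of the hindlimb list are Hoxa and Hoxd genes, which pattern both limbs, and the highest cover was at the Hoxa members. Neighbouring Hox loci overlap and so are not independent. With 1 member per overlapping locus, a choice made after seeing the data, 6 hindlimb loci had 20.6% and 9 others 3.70% (exact permutation test, p = 8.0e-04). The replicates differed at single genes by more than the lists did: Hoxc8 had 10.2% and 36.9%, Hoxc9 9.34% and 35.5%, and Hoxd11 13.2% and 3.42%.

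**Figure D4:**
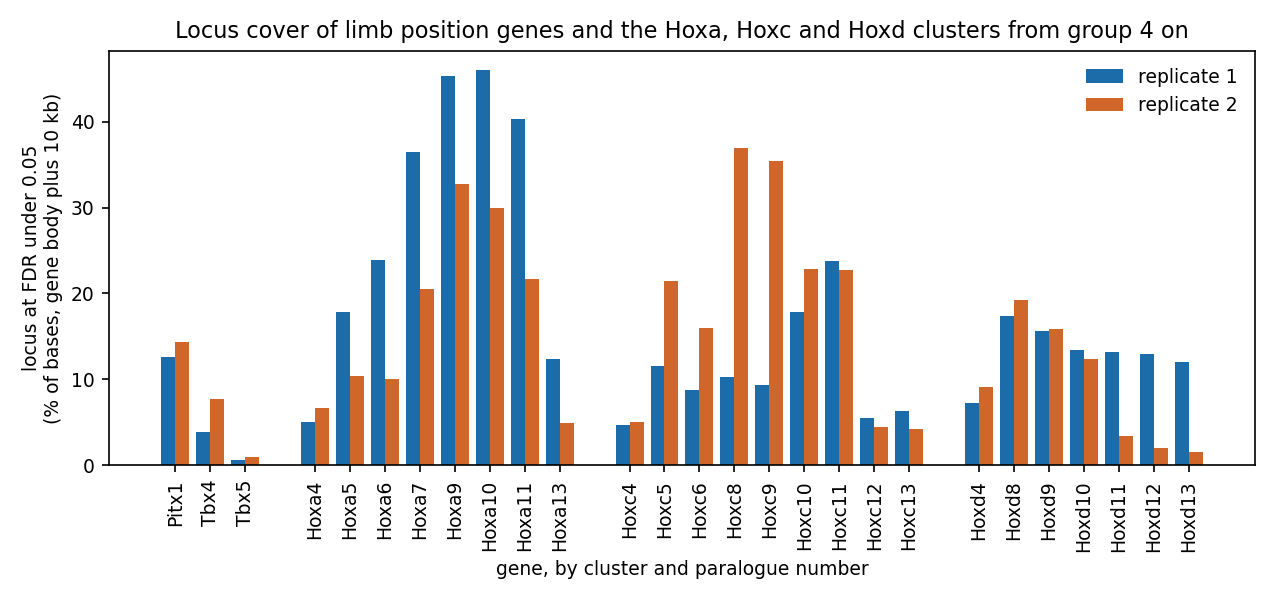
Percentage of listed bases per locus (y axis, gene body plus 10 kb on each side) for Pitx1, Tbx4, Tbx5 and genes of the Hoxa, Hoxc and Hoxd clusters from paralogue group 4 on (x axis, in order of paralogue number), in replicate 1 (blue) and replicate 2 (orange). Cover peaks at Hoxa9 and Hoxa10, up to 46.0%, and the replicates differ most at Hoxc8, with 10.2% and 36.9%.

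The CTCF core, bound by the architectural protein CTCF, was in 1.83% and 1.47% of footprints and in 0.00996% and 0.00645% of moved windows, odds ratios of 183 and 226, and the footprints over it had a median width of 29 bp in both libraries. The full NFI site was in 124 and 119 footprints and in 0 moved windows. NRF1 followed at 57.2 and 69.3, CRE at 9.24 and 14.2, and SP/KLF at 7.84 and 9.67. The E-box bound by myogenic factors was in 2.27% and 2.88% of footprints, the most of the 25 motifs, with odds ratios of 1.81 and 2.13. Its consensus is the shortest of the 25, and it was also the most frequent in moved windows, at 1.27% and 1.37%. Of the other muscle motifs, MEF2 had 0.628 and 1.28, MEF3 0.350 and 0.820, MCAT 0.766 and 0.945 and CArG, bound by SRF, 0.854 and 1.01. None of these was called in both replicates, and in replicate 1 alone MEF2 (adjusted p = 0.0288, Fisher's exact test), MEF3 (2.87e-05) and MCAT (3.66e-09) were lower than in moved windows. The lowest odds ratios among motifs called in both replicates were those of the glucocorticoid and androgen receptor site (0.236 and 0.256), GATA (0.275 and 0.277), the POU octamer (0.460 and 0.455), CRX (0.613 and 0.442) and the ERR site (0.579 and 0.572).

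Two-sided Fisher's exact tests with Benjamini-Hochberg adjustment called 10 motifs higher and 9 lower in both replicates. Against windows moved by 50 bp the order at the top changed, with mean odds ratios of 68.3 for NRF1, 58.1 for CTCF and 40.8 for NFI. The largest adjusted p of the higher ones was 1.33e-16 in replicate 1, for ETS, and 1.02e-14 in replicate 2, for NFY. Footprints were richer in G and C than the moved windows (65.1% and 62.5% against 56.1% and 54.2%), and motif letters in another order shift with that. Of the 10 higher motifs 8 exceeded every shuffle of their letters, EBF1 (4.35 and 6.78), YY1 (4.21 and 6.10) and ETS (3.77 and 4.89) included, while the E-box was matched by 1 of 20 shuffles and NFY by 2. Among the 9 lower motifs, only the glucocorticoid and androgen receptor site lay below every shuffle, a comparison added after seeing the data. Among distal footprints alone ETS (odds ratio 2.32), YY1 (2.33), NFY (1.02), AP-1, CRX and the ERR site were not called. Of the footprints in replicate 1, 51.7% were covered over at least 50% of their length in replicate 2, and 41.4% in the other direction (95% binomial intervals 51.5% to 51.9% and 41.2% to 41.6%).

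**Figure D5:**
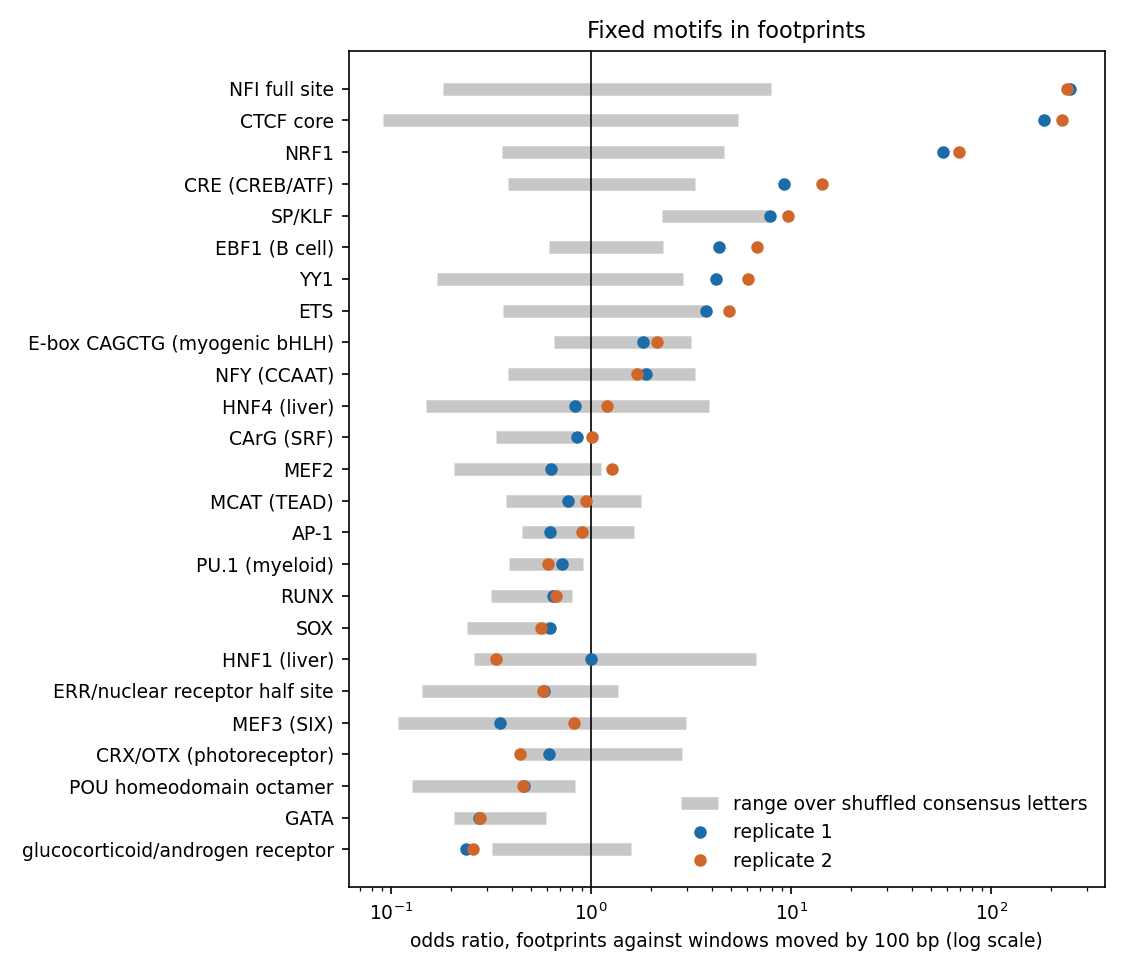
Odds ratio (x axis, log scale) of each fixed motif (y axis) in footprints against windows moved by 100 bp, in replicate 1 (blue) and replicate 2 (orange), over the range that shuffled letters of the motif gave (grey, at most 20 shuffles). CTCF (183 and 226), NFI and NRF1 lie far to the right of the grey ranges, and the E-box (1.81 and 2.13) lies within its own.

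Promoters and distal sites carried different motifs. Among 22058 shared promoter peaks and 53649 shared distal peaks, YY1 (odds ratio 64.3), ETS (18.9), NRF1 (12.8), SP/KLF (11.7) and CRE (6.75) were most enriched at promoters. On the distal side were NFI (0.0962), CTCF (0.148), the glucocorticoid and androgen receptor site (0.270), RUNX (0.342) and AP-1 (0.343). Myogenic E-boxes were in 24.8% of distal and 11.7% of promoter peaks, an odds ratio of 0.401, and MCAT sites of the TEAD factors had 0.379. Two-sided Fisher's exact tests with Benjamini-Hochberg adjustment called 7 motifs higher at promoters and 16 lower. Promoter peaks had 65.7% G and C against 54.0%, and within 10 classes of GC content 7 motifs were called in each direction. The E-box (0.402), AP-1 (0.538) and CTCF (0.326) were among those still lower at promoters, while RUNX (0.798) and MEF2 (0.959) were no longer called. On the promoter side the order changed within GC classes, to YY1 (24.1), ETS (19.4), NRF1 (5.90), NFY (5.20), CRE (5.17), POU (2.81) and SP/KLF (2.61), and in windows of 50 bp ETS (30.8) exceeded YY1 (15.4).

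Between the replicates, the promoters of contractile genes leaned toward replicate 2. Promoters open in both had a median log2 ratio of 0.44, replicate 2 over replicate 1, and the list values are relative to that. Pan-sarcomere and triad promoters had a median of 0.34, above all 10000 random lists, neuromuscular junction promoters 0.38 (percentile 99.7), fast myofibre promoters 0.22 (99.5) and fibroblast promoters 0.22 (99.1). Slow myofibre promoters had 0.27 (98.1) but −0.05 (76.8) with windows of 1000 bp. Endothelial promoters had −0.005 (97.6) and percentiles of 96.7 with those windows and 91.75 after quantile normalization, under which myogenic factors (97.54) lay just outside the middle 95% in their place. Without these alternatives 6 of 25 lists, the endothelial one included, lay outside the middle 95% of random lists, where chance gives 1.25. Against random lists matched also on CpG content, chosen after seeing the data, 2 remained, the sarcomere and neuromuscular junction lists. No p-value is given, since this sets 1 library against 1.

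The largest single differences were at promoters of genes outside the fixed lists. Sez6l2 had values of 9.65 and 0.423, 9930021J03Rik 12.9 and 2.63, Gm10719 82.7 and 18.1, Xntrpc 5.95 and 1.40, and Gja5, a connexin of the heart and arteries, 0.946 and 0.241. In the other direction Erap1 had 0.234 and 1.98, Pde3a 0.522 and 3.48, Gm17324 1.24 and 7.58, Cep57 3.61 and 20.2, and Gm14326 0.642 and 3.29. The spread of the log2 ratio over the 14267 promoters was 0.46 (SD), and the 10 genes are its extremes by choice.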

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

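The matching on CpG content for locus cover and for replicate differences and the bases listed in both replicates were chosen only after the results were seen. So were the test of hindlimb against forelimb and head loci and the single member per overlapping locus. The locus bases in place of promoter values and the comparison with all shuffled letters were also chosen then. Of 572 values under alternatives, 492 counted as unchanged. For single motifs and lists this meant that the call, or its absence, stayed, and direction was compared only where there had been a call. For counts it meant a change of at most 1.5-fold, and for the correlation one under 0.05. For other values it meant a move of less than the spread between replicates (for overlaps, the 95% binomial interval). For the single motifs and lists, 44 lost their call, 13 gained one and 3 that had been called changed direction. Motifs and lists without a call that changed direction were not counted among these 3.

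Stricter or wider choices moved the levels. The height correlation was 0.809 among peaks above the median value, and the X ratio there 0.234. The promoter share was 29.4% with 1000 bp, 32.5% among peaks above the median and 16.7% to 20.4% with a single replicate. Mean peak overlap over both directions was 61.2% with reciprocal overlap, 72.7% with the same number of peaks and 76.0% at the stricter threshold, in place of 71.2%, and mean overlap of listed bases 78.8% at that threshold, in place of 76.1%. Mean footprint overlap, 46.5%, was 54.6% at 1 bp and 57% inside shared peaks. Among peaks above the median, 1 list in place of 4 was higher at promoters. The 7 lower lists became 4 to 5 with a single replicate and 3 within CpG classes. Locus cover was lower in 0 lists with CpG matching and in 2 with bases listed in both replicates, in place of 1. List differences between replicates numbered 2 in place of 6 with CpG matching. Motifs below every shuffle numbered 1 in place of 9. The 16 motifs rarer at promoters became 10 in windows of 50 bp and 7 within GC classes, where MEF3 (1.13), CArG (1.09) and GATA (1.03) crossed to the promoter side without passing the test. The HNF1 site had too few matches for a value within GC classes. The cause of these shifts was not tested. A stricter set of footprints was not run for overlap or motifs, since all footprints carry 1 value. No paired analysis was possible because there is only 1 group.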

Other observations

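The tests of the macrophage counts, of a lower myofibre share and of the blocks were chosen only after the results they concern were seen, as were the locus bases per replicate, the peaks of 1 library alone and the ratios of shared peaks by motif; the gene names in the next paragraph were also chosen after their values were seen.

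Macrophage promoters were among those that opened in replicate 2 alone. They were open in 2 of 14 cases in replicate 1 and in 9 of 14 in replicate 2, where Cd68 had a value of 0.833, Fcer1g 0.781, the complement genes C1qc, C1qb and C1qa 0.763, 0.575 and 0.558, Csf1r, the receptor for the macrophage growth factor, 0.616, and Mrc1 0.299, all without a peak in replicate 1. Of promoters closed in replicate 1, 4 of 5 developmental sarcomere promoters (Tnnt2, Chrng, Mymk and Mymx) and both of the neuromuscular junction (Chrnd and Chrne) also opened. Over all genes, 427 of 7234 promoters closed in replicate 1 (5.90%) opened in replicate 2. In the other direction it was 410 of 7217 (5.68%). Macrophage loci had 2.74% of bases listed in replicate 1 and 4.93% in replicate 2, with a median log2 ratio of 0.60, above all of 10000 random lists. The loci of C1qa, C1qb and C1qc overlap, so the 14 macrophage genes stand for 12 separate loci. The random lists made no allowance for such neighbours. In the same measure 8 of 26 lists lay above the middle 95% of random lists, where chance puts 1.3 outside it: fast myofibre (0.26), developmental sarcomere (0.30), sarcomere and triad (0.28), neuromuscular junction (0.31), satellite cell (0.26), fibroblast (0.32), endothelial (0.38) and macrophage. None of the lists of hepatocytes, neurons, germ cells, photoreceptors, pancreas or keratinocytes did. Several lists of muscle or of cells that the tissue could hold did not either. These were myogenic factors, slow myofibres, tendon, pericytes with smooth muscle, lymphocytes, Schwann cells, erythroid cells and adipocytes.

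Peaks of a single library differed in their motifs. Among 40460 distal peaks of replicate 2 alone and 17344 of replicate 1 alone, the myogenic E-box was in 25.3% and 14.4% (odds ratio 2.15 within 10 classes of GC content, 95% interval 2.05 to 2.26), MEF2 had an odds ratio of 4.63 (2.91 to 7.36), MEF3 2.80 and AP-1 2.03. CTCF, with 0.547 (0.460 to 0.651), and NFI, with 0.228 (0.154 to 0.339), went the other way. Shared distal peaks showed the same split: the median log2 ratio of replicate 2 over replicate 1 was 0.58 with MEF2, 0.49 with the E-box and 0.23 over all 53649, but −0.34 over the 4148 with CTCF. The largest median of the motifs, 0.62, was at the 94 peaks with the glucocorticoid and androgen receptor site, so the rise was not limited to muscle motifs. Relative to peaks of like GC content and value the medians were 0.295 for that site, 0.25 for MEF2, 0.21 for the E-box and −0.42 for CTCF.

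The gain of macrophage promoters in replicate 2 was weighed first. With about the same number of highest peaks as in replicate 1, macrophage promoters open in replicate 2 still numbered 8 of 14. Over all genes 14273 promoters were then open against 14677 in replicate 1. The larger number of sites called in replicate 2 thus did not by itself give the gain. The replicate 2 values were known when this test was chosen, and equal numbers of peaks do not equalize sensitivity. More sensitive calling in replicate 2 is therefore not excluded. A lower share of myofibre nuclei would raise every other cell type and lower sarcomere and triad promoters. Their centred median log2 ratio of 0.34, above all random lists, goes the other way. That value was known before this test was chosen, so it adds no independent support, and promoter values do not count nuclei. The PU.1 site, bound by the main myeloid factor, was more frequent in distal peaks of replicate 2 alone. The odds ratio was 1.66 (95% interval 1.3 to 2.12), a direction written down for more macrophage nuclei before the value was seen. More macrophage nuclei may account for the gain. It stays open, because the photoreceptor motif CRX had 2.15 in the same comparison, set beside it afterwards, because the 314 shared distal peaks with a PU.1 site had a median log2 ratio only 0.02 above peaks of like GC content and value, and because Adgre1, Spi1, Tyrobp, Cx3cr1 and Cd163 had no promoter peak in either library.

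The lean of myofibre and fibroblast promoters toward replicate 2 was weighed next. Promoter CpG content could account for part of it, since 2 of the 5 lists concerned (fast, slow, sarcomere, neuromuscular junction and fibroblast) stayed above the middle 95% of random lists matched on it, between the bounds set beforehand of 1 and 4. A larger share of myofibre nuclei could not be excluded by the fibroblast list, which such a share should lower: it lay at percentile 97.21 of the matched lists, just inside the middle 95%. A rise common to all sites, from a higher signal over background, is argued against by CTCF sites, which should rise with the rest. Their shared distal peaks had a median log2 ratio of −0.34 before centring. The lower frequency of CTCF in peaks of replicate 2 alone was, however, already known when this was tested. A higher signal at most sites is not excluded: peak values summed to 195188 in replicate 1 and 259813 in replicate 2. The median log2 ratio was 0.44 at promoters open in both and 0.23 over all shared distal peaks. Differences in digestion or in fragment length were not analysed here, and while these tests concern the mix of cells in each sample, the design has 1 group and no biological difference between samples was tested.

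Blocks listed to a far larger part in 1 replicate than in the other were weighed last. There were 10 runs of at least 15000 bp with over 40% of bases listed in one library and under 15% in the other, 8 in replicate 1 and 2 in replicate 2, with 48.7% to 87.1% listed in one and 0% to 8.81% in the other; examples are those over Pld4 and Ahnak2 (0% and 87.1%), over Col6a1 (3.36% and 66.1%) and over Adcy4 and Ripk3 (85.5% and 3.49%). A lower local calling threshold is a candidate explanation: of the peaks in the blocks that only 1 library had, 67.1% lay below the limit of the lowest 10% of that library's peaks elsewhere. Peaks of 1 library alone are weak in general, and outside the blocks 34.5% of those in replicate 1 and 21% of those in replicate 2 lay below it, a rate that 9 of the 10 blocks exceeded, with bounds set after weak values in the blocks had been seen. No other explanation was tested, and locus cover of single genes in 1 library can rest on such blocks.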
